A study of Homo sapiens with 6 samples.

How the data were processed

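RNA was measured by sequencing in 6 libraries of SUM159, a human triple-negative breast cancer cell line. Of these, 3 libraries came from cells with the pCMV6 empty vector (EV) and 3 from cells with pCMV6-FoxQ1 (FoxQ1). Per the labels' protocols, the cells were plated in triplicate without treatment, harvested with trypsin, and total RNA was extracted with a column kit. The groups and replicate numbers were taken from the sample titles and the transfection labels. The labels do not say whether the dishes of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

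The authors deposited a table of 48162 genes with Ensembl identifiers, gene names, coordinates, lengths and biotypes. Raw read counts per gene were deposited as whole numbers, and HTSeq 0.6.1 is named for this kind of step in the submitters' processing notes. Those notes name the builds GRCh37 and hg19, DESeq2 without a version, and edgeR 3.16.5. The aligner, the annotation release, the strand setting and the read filters are not given in the sources used here. Coordinates below are those of the deposited table, in hg19. The deposited FPKM values of each library were the counts per kilobase of the listed gene length and per 1e6 counts of the library's table total. Recomputing them from the counts gave a largest relative difference of 4.97e-12. A second deposited table held the same FPKM values. The deposited table also held the authors' group means of FPKM and a normalized count signal per group, per the file headers, and neither was used in a test. The authors' deposited log2 fold changes, p-values and adjusted p-values for FoxQ1 over EV, per the file headers, were compared with the fit described next. Every row of the table had a gene identifier, so no row was left out of the library totals.

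The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, library sizes were scaled by TMM, and a quasi-likelihood test (glmQLFit and glmQLFTest) compared the groups with no covariate. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The standard error (SE) of a log2 fold change was its absolute value divided by the square root of the F statistic. Levels are CPM, counts per 1e6 counts of the library after TMM scaling, as mean ± SD. Where one group had no reads, the fold was computed against a floor of 3 reads over the group's 3 libraries and is a lower bound. Where one group had 1 to 3 reads in all, the ratio is given with an exact binomial 95% interval, which covers counting error only. Wilson intervals of shares treat reads or genes as independent, so they too cover counting error only and not the spread between libraries. The library totals of 22605912 to 30364318 counts set the precision. On simulated counts with the real means and library sizes, the same steps run on 14701 genes recovered 18% of genes changed 1.25-fold, 56% at 1.5-fold, 84% at 2-fold and 100% at 4-fold in the comparison of FoxQ1 with EV. Only 50 genes were changed at each of these folds, far fewer than passed in the real comparison. Of 138 simulated calls, 9 (6.52%) were false.

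Before the data were examined, 32 gene lists and 5 check lists of markers and RNA handling were fixed. A list with at least 5 tested members was tested with camera from limma 3.58.1 with a preset inter-gene correlation of 0.01, and p-values were adjusted over the 33 lists that qualified. Camera with an estimated correlation, camera on ranks and the rotation test fry were run beside it. Camera compares a list with the other genes, while fry asks whether a list's genes move one way on balance. Member counts were made at an adjusted p of 0.05 over all genes and again adjusted over the list alone. The named genes followed a rule also fixed then. It takes FOXQ1, the 6 largest rises and 6 largest falls among protein-coding genes past the threshold with mean CPM of at least 1 and non-overlapping groups, and 5 more of each with mean CPM of at least 50. From each list it takes up to 4 members with the largest change past the threshold and mean CPM of at least 1, or the 2 most abundant members if none qualified, and every tested gene of the FoxQ1-linked list. Untested members of that list and genes overlapping a named one are mentioned as well. Other genes named outside this rule are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

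The alternatives were RLE size factors, library totals without TMM, DESeq2 1.42.0, limma with a trend on log2(FPKM + 1) and log2(FPKM + 0.1) with mean FPKM of at least 1, the FPKM test without a filter, edgeR without a filter and with mean CPM of at least 1, each library left out, a replicate block, and FOXQ1 left out of the counts. Fold changes on the log2(FPKM + pseudocount) scale understate the change of low genes. After the data were seen, 2 alternatives were added. One left out all genes of the mitochondrial chromosome, among them the 13 mitochondrially encoded mRNAs. The other subtracted from each gene the median log2 fold change of its 40 neighbouring genes as an offset.

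Regional medians were taken over 313 non-overlapping windows of about 40 neighbouring genes with mean CPM of at least 1, chromosome Y and mitochondrial genes left out, and set against 1000 random orders of the genes. GC content came from the longest GENCODE v29 transcript with the same Ensembl gene identifier, found for 97.6% of these genes, and no coordinate of that annotation was used. Figures were drawn with matplotlib 3.10.9. Because the strand setting is not given, reads of overlapping genes on opposite strands may not be separable. Near-identical copies, such as HSPA1A and HSPA1B, the AKR1C genes, the GAGE and PAGE families, and ribosomal protein genes with processed pseudogenes, may share or lose reads in counting. Gene-level counts do not separate transgene reads from reads of the endogenous FOXQ1 gene.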

Results

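The comparison asked which transcripts differ between SUM159 cells overexpressing FoxQ1, a forkhead transcription factor, and cells with the empty vector. RNA was sequenced from 3 EV and 3 FoxQ1 libraries. The library totals were 25125318, 25319922 and 22605912 counts for EV replicates 1 to 3 and 24073845, 30364318 and 24809061 counts for FoxQ1 replicates 1 to 3. Between 21831 and 22879 genes had at least 1 read in a library. Log CPM values correlated across genes at 0.994 within EV and at 0.989 to 0.994 within FoxQ1, where FoxQ1 replicate 1 stood apart from the other FoxQ1 libraries. The chi-square of the counts per degree of freedom was 25.3 and 38 between it and FoxQ1 replicates 2 and 3. It was 5.65 between replicates 2 and 3, and 2.16 to 3.67 within EV. The first principal component held 82.8% of the variance.

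The overexpressed gene FOXQ1 (ENSG00000164379, chromosome 6, 1312675 to 1314992, plus strand, 2318 bases) was higher in every FoxQ1 library than in every EV library. It had 393, 334 and 331 reads in the EV libraries and 852, 1149 and 1016 reads in the FoxQ1 libraries. Its level was 14.4 ± 1.24 CPM (SD, n = 3) in EV and 38.3 ± 1.86 CPM (n = 3) in FoxQ1. This was a 2.66-fold rise, with a log2 fold change of 1.41 (SE 0.0868, edgeR adjusted p = 9.88e-07). These reads may come from the transgene, the endogenous gene or both, since gene-level counts do not separate them.

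The interleukin 1 genes IL1A and IL1B, the EGF receptor ligand genes AREG, TGFA and EREG and the immediate early gene EGR1 rose in FoxQ1 cells. Of the tested members, 13 of 22 interferon-stimulated genes, 13 of 18 NRF2 target genes and 9 of 12 heat shock genes fell. As lists these 3 passed camera with its preset correlation and were lost with an estimated correlation (adjusted p = 0.181, 0.324 and 0.36). Of 14949 tested genes, 7132 (47.7%) passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, 3594 higher and 3538 lower in FoxQ1. Among them 1823 changed at least 2-fold, 966 upward and 857 downward. The biological coefficient of variation was 8.37%, which let small differences pass the test. With limma on log2(FPKM + 1), 538 genes passed with at least a 2-fold change.

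**Figure D1:**
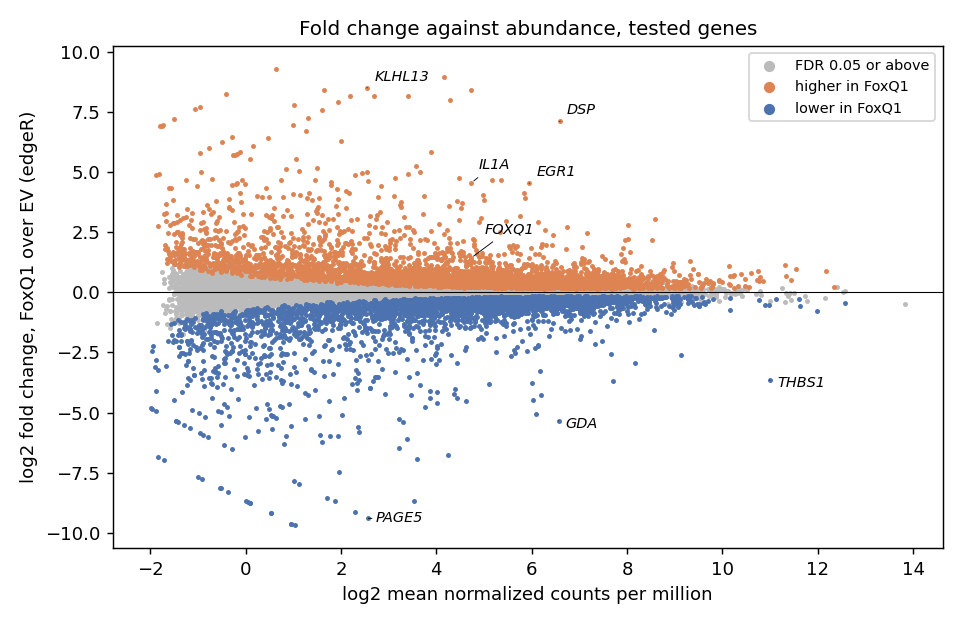
Log2 fold change of FoxQ1 over EV (vertical) against log2 mean CPM (horizontal), one point per tested gene. Genes past an adjusted p of 0.05 are orange when higher and blue when lower in FoxQ1, and grey points did not pass. The 3594 higher and 3538 lower genes spread over the whole range of abundance, with FOXQ1 at a log2 fold change of 1.41.

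Many of the largest changes were between near silence and clear expression. KLHL13, an adaptor of a cullin-3 ubiquitin ligase on chromosome X (117031776 to 117251303), rose from 2 reads in EV to 916 reads in FoxQ1, a ratio of 428 (95% counting interval 118 to 3537). ALDH1A1, a retinaldehyde dehydrogenase on chromosome 9 (75515578 to 75695358), rose from 3 to 1017 reads, a ratio of 317 (108 to 1538). The organic cation transporter gene SLC22A2 had 1 read in EV and 492 in FoxQ1, a ratio of 459 (82.1 to 18180), and overlaps the noncoding gene RP1-276N6.2. RIMKLB (340-fold), EFCAB4B (289-fold) and PALD1 (253-fold) completed the 6 largest rises. In the other direction, the membrane mucin gene MUC15 (chromosome 11, 26580580 to 26593780, overlapping ANO3) and the tetraspanin gene TSPAN15 (chromosome 10, 71211229 to 71267425) each had 286 reads in EV and none in FoxQ1, at least 102-fold lower. BCHE, which encodes butyrylcholinesterase, and GAGE1, of a family of near-identical cancer-testis genes, each had 211 reads in EV and none in FoxQ1, at least 75.3-fold lower. PAGE5 had 876 reads in EV and 1 in FoxQ1, and CPPED1 had 727 and 1.

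Among abundant transcripts, the desmosomal plaque gene DSP rose most, from 1.38 ± 0.284 CPM in EV to 191 ± 9.55 CPM in FoxQ1 (SD, n = 3 each, 137-fold). It lies on chromosome 6 from 7541808 to 7586950. EGR1, an immediate early transcription factor gene (chromosome 5, 137801179 to 137805004), rose 23.2-fold to 118 ± 4.35 CPM (n = 3). The netrin receptor gene NEO1 rose 17.5-fold and the tRNA methyltransferase gene ALKBH8 8.99-fold. GDA, which encodes guanine deaminase (chromosome 9, 74729511 to 74872109), fell most, from 185 ± 8.15 to 4.52 ± 0.317 CPM (n = 3 each, 40.8-fold). DNM1 fell 33.7-fold, CPED1 22.5-fold, the adhesion molecule gene MCAM 19.3-fold and the export pump gene ABCC2 13.6-fold. DNM1 overlaps CIZ1.

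**Figure D2:**
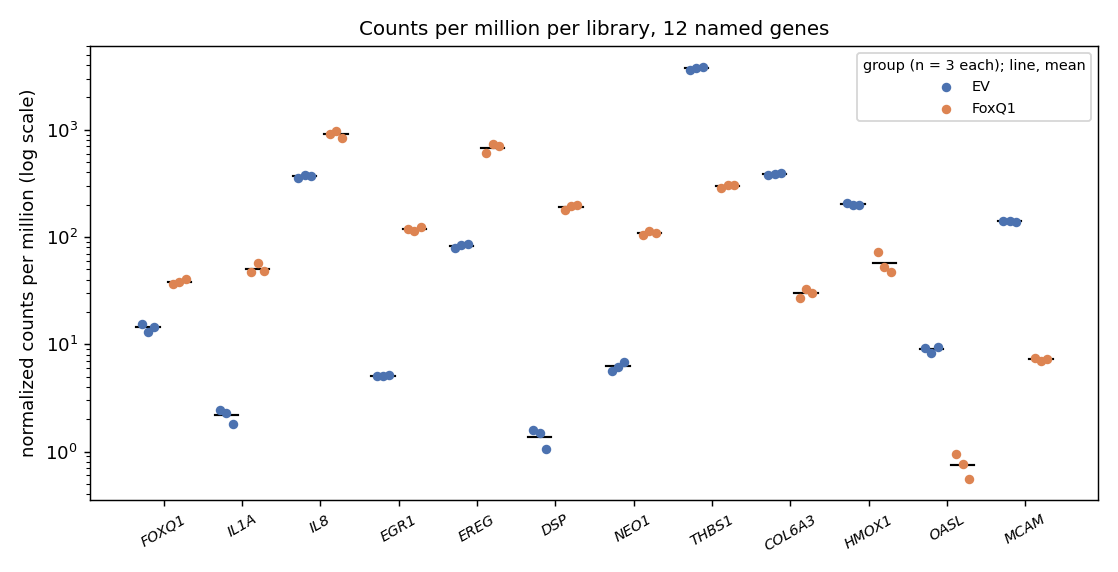
Normalized CPM per library (log scale) of 12 named genes in EV (blue, n = 3) and FoxQ1 (orange, n = 3), with a line at each mean. The 3 FoxQ1 libraries lie beyond the 3 EV libraries for each gene, from FOXQ1 at 14.4 against 38.3 CPM to THBS1 at 3774 against 300 CPM.

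Cytokine and chemokine genes responsive to NF-kB were higher as a list. Of 19 tested members, 12 rose, 1 fell and 6 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 5.78e-06, and adjusted p = 0.324 with an estimated correlation). The interleukin 1 genes led, IL1A with 2.18 ± 0.34 CPM in EV and 50.8 ± 6.03 CPM in FoxQ1 (SD, n = 3 each, 23.2-fold) and IL1B with a 21.8-fold rise. LIF rose 13.1-fold, CSF2, which encodes GM-CSF, rose 5.61-fold, and IL8 rose 2.45-fold to 905.5 ± 72.5 CPM (n = 3). Immediate early genes were higher too, with 10 of 13 members up and 1 down (camera adjusted p = 3.09e-05, and adjusted p = 0.324 with an estimated correlation), including FOS (6.46-fold), FOSB (4.19-fold, overlapping ERCC1) and BTG2 (1.88-fold). Of 23 tested growth factor and receptor genes 12 rose and 7 fell (camera adjusted p = 0.00451, and adjusted p = 0.537 with an estimated correlation). The EGF receptor ligand genes AREG (11.4-fold), TGFA (9.96-fold) and EREG (8.23-fold, to 682 ± 63.9 CPM, n = 3) were among the risers, as was HGF (5.77-fold). This last list missed the threshold in the FPKM tests and on ranks.

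Interferon-stimulated genes were lower. Of 22 tested members 13 fell, 2 rose and 7 did not pass, with 14 falls when adjusted over the list alone (camera adjusted p = 3.49e-05, and adjusted p = 0.181 with an estimated correlation). IFIT2 fell 13.9-fold, OASL 11.9-fold from 9.02 ± 0.584 CPM (n = 3), HERC5 9-fold and IFIT1 7.4-fold. Some of these were scarce, with 137 reads in EV for HERC5, and IFIT1 and IFIT2 overlap LIPA. The list missed the threshold in the log2(FPKM + 0.1) test. Of 12 genes of MHC class I presentation, 4 fell and none rose (3 falls when adjusted over the list alone), led by HLA-F (4.44-fold) and followed by TAP1 (1.42-fold), NLRC5 (1.34-fold) and PSMB9 (1.32-fold). That list did not pass camera (adjusted p = 0.296) except in the unfiltered FPKM test (adjusted p = 0.0487). The PSMB9 call was lost in 8 of 18 alternatives (adjusted p up to 0.162), among them leaving out any EV library or FoxQ1 replicate 2 or 3. TAP1 and PSMB9 overlap in the annotation.

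Targets of NRF2, the regulator of antioxidant and detoxifying enzymes, were lower. Of 18 tested members 13 fell, 1 rose and 4 did not pass, and the counts were the same over the list alone (camera adjusted p = 3.78e-05, and adjusted p = 0.324 with an estimated correlation). The aldo-keto reductase genes AKR1C1 (4.52-fold) and AKR1C3 (2.79-fold), OSGIN1 (3.68-fold) and the haem oxygenase gene HMOX1 (3.56-fold, from 203 ± 5.29 to 57.2 ± 12.9 CPM, n = 3 each) fell most. AKR1C genes are close copies whose reads the counting may split. AKR1C1 and AKR1C3 lie in a lowered region of chromosome 10. With regional medians subtracted their log2 fold changes went from -2.18 to -1.7 and from -1.48 to -1.01, while HMOX1 went from -1.83 to -2.04. The NRF2 list then had 11 falls and 1 rise and still passed camera with its preset correlation (adjusted p = 7.83e-05). Heat shock genes were lower as well, with 9 of 12 down and none up, or 10 down over the list alone (camera adjusted p = 5.21e-05, and adjusted p = 0.36 with an estimated correlation). HSPA1A fell 9.28-fold and its near-identical copy HSPA1B 4.12-fold, HSPB1 1.97-fold and DNAJB1 1.81-fold. The other stress lists did not pass camera with its preset correlation, but some alternatives called them. In the unfolded protein response list 8 of 16 genes rose and 3 fell (9 and 3 over the list alone, camera adjusted p = 0.0816), with CRELD2 (2.11-fold), HYOU1 (2.05-fold), HSP90B1 (1.69-fold) and EDEM1 (1.6-fold) highest. HYOU1 went from a log2 fold change of 1.04 to 0.5 with regional medians subtracted. In the ATF4 and amino acid stress list 10 of 18 rose and 1 fell (11 and 1 over the list alone, camera adjusted p = 0.0816), among them CHAC1 (4.58-fold), SESN2 (3.76-fold) and ATF3 (1.44-fold) upward and VLDLR downward (3.71-fold). Of 19 p53 target genes 10 rose and 3 fell (camera adjusted p = 0.0816), including GDF15 (2.96-fold) and the cell cycle inhibitor gene CDKN1A (2.08-fold). Over 21 alternatives the adjusted p ranged from 0.00134 to 0.324 for the unfolded protein response list, from 0.00388 to 0.803 for the ATF4 list and from 0.00107 to 0.324 for the p53 list, which were called in 6, 10 and 8 of them.

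Extracellular matrix genes moved in opposite directions. Of 24 tested collagen, laminin and proteoglycan genes 11 fell, 8 rose and 5 did not pass, with 12 falls over the list alone (camera adjusted p = 5.21e-05, and adjusted p = 0.327 with an estimated correlation). COL6A3 (chromosome 2, 238232646 to 238323018) fell 13-fold from 389 ± 9.29 CPM (n = 3), THBS1, which encodes thrombospondin 1, fell 12.6-fold from 3774 ± 122 CPM (n = 3), and COL1A1 fell 6.13-fold. The call was lost on ranks and in the FPKM tests. Among 12 matrix protease and inhibitor genes 4 rose and 3 fell (camera adjusted p = 0.0263, and adjusted p = 0.324 with an estimated correlation). The list's median log2 fold change of 0.23 turned to -0.18 with DESeq2 (adjusted p = 0.0163) and to -0.11 without a count filter (adjusted p = 0.0395). The plasminogen activator genes PLAU (9.58-fold) and PLAT (3.88-fold) rose, and ADAMTS1 fell 1.48-fold. PLAU overlaps C10orf55. The protease call was also lost on ranks, in the FPKM tests and without EV replicate 1, EV replicate 3 or FoxQ1 replicate 1.

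Members of the mesenchymal and epithelial lists moved in both directions. Of 24 tested mesenchymal and EMT genes 11 rose and 9 fell (camera adjusted p = 0.521). POSTN (5.64-fold), TNC (4.65-fold, to 426 ± 33.2 CPM, n = 3) and PDGFRA (3.58-fold) rose, and S100A4 fell 10.3-fold. Of 13 tested epithelial junction and keratin genes 3 rose and 4 fell (3 and 6 over the list alone, camera adjusted p = 0.266). Beside the rise of DSP, KRT5 fell 6.01-fold, MUC1 4.15-fold and KRT8 1.29-fold. The KRT8 call was lost without EV replicate 1 or FoxQ1 replicate 2 and with regional medians subtracted (adjusted p up to 0.0991). By fry, both the mesenchymal and the epithelial list were higher on balance (adjusted p = 0.00432 and 0.000235). The epithelial list's median log2 fold change was 0.02 and its mean was -0.05. TGF-beta target genes split 10 up and 5 down of 18 (camera adjusted p = 0.933), with a median of 0.23 and a mean of -0.24. TGFB2 fell 16.4-fold and IGFBP3 12.6-fold, while LTBP2 rose 2.12-fold and SMAD7 1.89-fold. YAP and TAZ target genes split 5 up and 10 down of 16 (camera adjusted p = 0.127), with ANKRD1 16.6-fold, CYR61 1.88-fold and AJUBA 1.61-fold lower and AMOTL1 2.71-fold higher. By fry this list was lower on balance (adjusted p = 0.00287). SMAD7 went from a log2 fold change of 0.92 to 0.34 and AJUBA from -0.69 to -0.32 with regional medians subtracted.

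**Figure D3:**
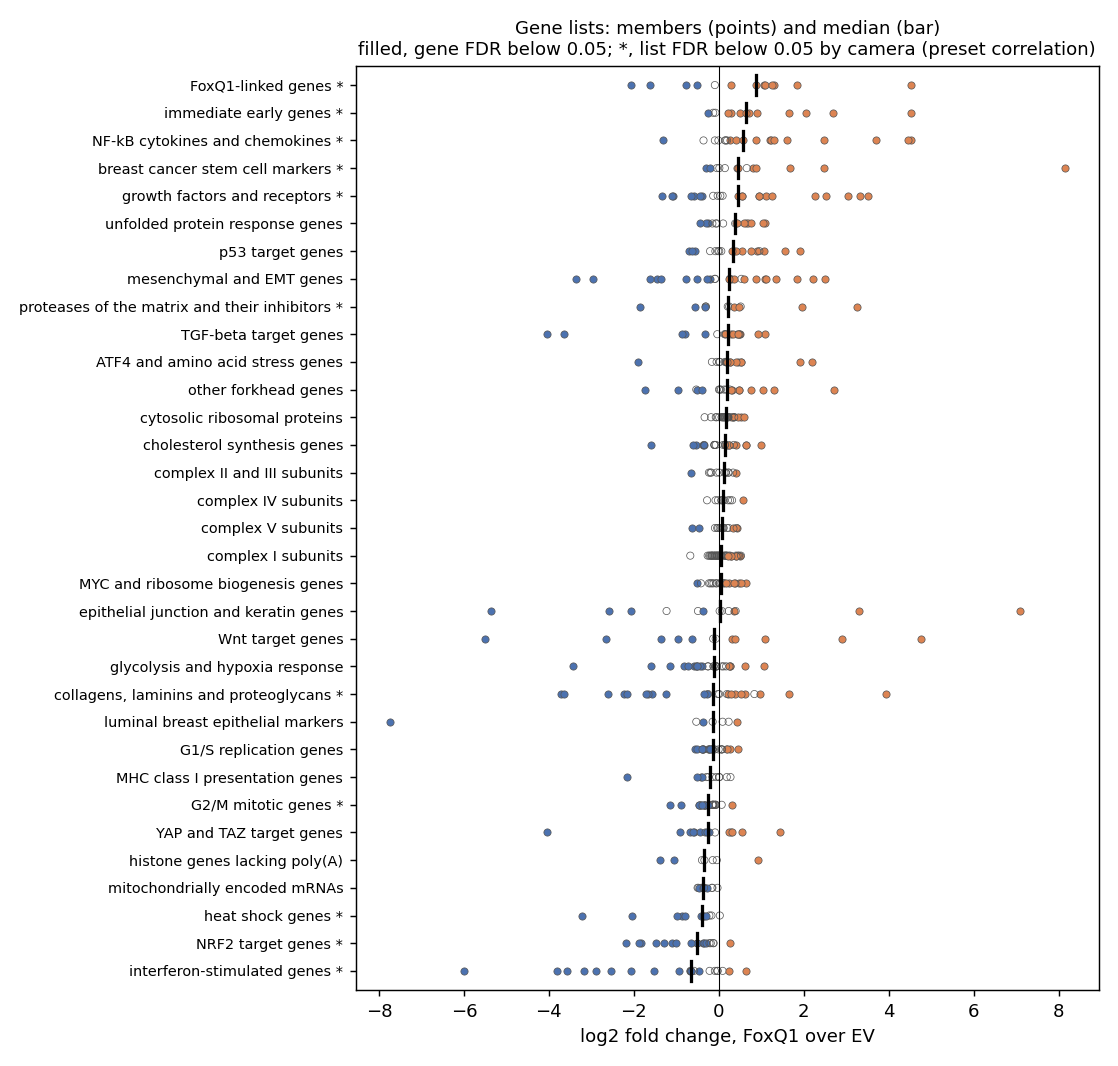
Log2 fold change of FoxQ1 over EV (horizontal) of each tested member of the 33 tested lists (rows), filled where the gene passed an adjusted p of 0.05, with a bar at the list median and a star where camera with its preset correlation passed. The starred lists are 6 with higher and 5 with lower expression, and all 11 miss the threshold with an estimated correlation.

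Breast cancer stem cell markers were higher. Of 13 tested members 7 rose and 2 fell (camera adjusted p = 0.000426, and adjusted p = 0.181 with an estimated correlation). Beside ALDH1A1, SOX9 rose 5.55-fold, the integrin gene ITGA6 3.21-fold to 410 ± 23.2 CPM (n = 3) and KLF4 1.84-fold. Wnt target genes split evenly, 5 up and 5 down of 12 (camera adjusted p = 0.914). RNF43 rose 27-fold and LEF1 7.44-fold, while the Wnt inhibitor gene DKK1 fell 6.31-fold and SP5 2.55-fold. Of 19 other forkhead genes 8 rose and 4 fell (9 and 5 over the list alone, camera adjusted p = 0.611), with FOXP2 (6.61-fold), FOXF1 (2.48-fold) and FOXP1 (2.06-fold) higher and FOXA2 3.34-fold lower. Only 4 hair shaft and melanocyte genes were testable, too few for camera, and 2 of them fell, MITF 1.7-fold and HOXC13 1.4-fold.

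A list of 15 genes linked to FoxQ1, by background knowledge of which part may come from these cells, is not independent evidence of a direction. Of its 13 tested members 8 rose, 4 fell and VIM did not pass, with the same counts over the list alone (camera adjusted p = 0.000712, and adjusted p = 0.181 with an estimated correlation). Besides IL1A, IL8, PDGFRA and CDKN1A, VEGFA rose 2.37-fold, the fibronectin gene FN1 2.13-fold to 1544 ± 113 CPM (n = 3), ZEB2 1.85-fold and CDH2 1.22-fold. DACH1 fell 4.2-fold, PDGFRB 3.04-fold, SNAI1 1.7-fold and TWIST1 1.42-fold. VIM was at 729 ± 10.3 CPM in EV and 684 ± 94.2 CPM in FoxQ1 (n = 3 each). CDH1, with 4 reads in EV and 1 in FoxQ1, and NRXN3, with 3 and 2, were too scarce to test. The call of this list was lost on ranks and in the unfiltered FPKM test. CDH2 lies in a region of chromosome 18 whose genes shifted upward together, and with the regional median subtracted its log2 fold change was -0.26 in place of 0.28. FN1 lies in a raised region of chromosome 2 and went from 1.09 to 0.54.

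Mitotic genes were lower by small amounts. Of 23 G2/M genes 12 fell and 1 rose (camera adjusted p = 0.0132, and adjusted p = 0.305 with an estimated correlation), including AURKB (2.2-fold), CDK1 (1.84-fold), AURKA (1.39-fold) and TOP2A (1.39-fold). AURKB and TOP2A lie on chromosome 17, where neighbouring genes were lower together, and with the regional median subtracted AURKB went from a log2 fold change of -1.14 to -0.43 and TOP2A did not pass (log2 fold change -0.082). The G1/S replication list split 3 up and 9 down of 22 (4 and 11 over the list alone, camera adjusted p = 0.442), with CDC6 (1.47-fold), PCNA (1.43-fold) and RFC4 (1.32-fold) lower and MCM5 1.37-fold higher. The unfiltered FPKM test called this list (adjusted p = 0.035). In the MYC and ribosome biogenesis list 7 of 20 rose and 1 fell (camera adjusted p = 0.521). MYC rose 1.56-fold to 519 ± 14.5 CPM (n = 3), NCL 1.43-fold and BOP1 1.38-fold, and MYBBP1A fell 1.42-fold. All 4 lie in regions shifted the same way. With regional medians subtracted MYC went from a log2 fold change of 0.65 to 0.16, the calls of NCL (0.09) and BOP1 (0.05) were lost, MYBBP1A changed sign without passing (0.1), and 2 members of the list rose and 4 fell. In the cell cycle lists CDC6 went from -0.56 to -0.18, MCM5 from 0.46 to 0.26 and CDK1 from -0.88 to -0.56, while RFC4 went from -0.4 to -0.68.

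Metabolic lists did not pass camera with its preset correlation. Of 28 glycolysis and hypoxia genes 5 rose and 11 fell (camera adjusted p = 0.204), with ALDOC (3.04-fold), EGLN3 (2.21-fold) and ADM (1.76-fold) lower and NDRG1 2.1-fold higher. The glycolysis and hypoxia list was called in 5 of 21 alternatives, with an adjusted p from 0.035 to 0.916 (0.0452 by fry). NDRG1 lies in a raised region of chromosome 8, and its log2 fold change went from 1.07 to 0.52 with regional medians subtracted. Of 23 cholesterol synthesis genes 8 rose and 5 fell (camera adjusted p = 0.846), with INSIG1 3-fold lower and SC5D (1.99-fold), SREBF2 (1.57-fold) and SQLE (1.55-fold) higher. All 4 lie in regions whose genes shifted together the same way. With regional medians subtracted their log2 fold changes went from -1.59 to -0.71 for INSIG1, from 0.99 to 0.43 for SC5D, from 0.65 to 0.34 for SREBF2 and from 0.63 to 0.25 for SQLE. Of 30 cytosolic ribosomal protein genes 5 rose and none fell (3 over the list alone, camera adjusted p = 0.458), RPS20 by 1.51-fold, RPL3 by 1.45-fold, RPL8 by 1.37-fold and RPL30 by 1.27-fold, and with regional medians subtracted none passed. The list was called only without FoxQ1 replicate 3 (adjusted p = 0.0385). The RPS20 call was lost when any EV library was left out and the RPL30 call without EV replicate 3. Each of these 4 genes was highest in FoxQ1 replicate 1, though none lost its call without that library. The median log2 fold change of the whole ribosomal list was 0.18, but ranged from -0.0799 to 0.323 over 21 alternatives. RPS20 was at 439, 278 and 235 CPM in FoxQ1 replicates 1 to 3, against 211 ± 5.14 CPM in EV (n = 3).

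Few respiratory chain subunits differed. The medians of the nuclear-encoded lists changed sign over 21 alternatives, and no alternative called these lists. They ranged from -0.1013 to 0.1615 for complex I and from -0.0448 to 0.1889 for complexes II and III. For complex IV they ranged from -0.1145 to 0.243 and for complex V from -0.0671 to 0.1707. Of 37 complex I genes 6 rose and none fell (2 over the list alone, camera adjusted p = 0.611), with NDUFA11 at 1.42-fold, NDUFA10 at 1.33-fold, NDUFS1 at 1.32-fold and NDUFB2 at 1.22-fold higher. NDUFA10 and NDUFS1 lie in a region of chromosome 2 whose genes were higher together, and neither passed with regional medians subtracted. Of 13 complex II and III genes CYC1 rose 1.32-fold and SDHD fell 1.56-fold (camera adjusted p = 0.934). CYC1 did not pass with regional medians subtracted, and SDHD went from a log2 fold change of -0.65 to -0.38. Of 11 complex IV genes COX6C rose 1.5-fold (none over the list alone, camera adjusted p = 0.782). Of 14 complex V genes ATP5A1 (1.35-fold) and ATP5G3 (1.26-fold) rose and ATP5C1 (1.55-fold) and ATP5H (1.38-fold) fell, or 1 and 2 over the list alone (camera adjusted p = 0.914). With regional medians subtracted, no complex IV or V gene passed and 3 complex I genes did, without NDUFB2. Of the 13 mitochondrially encoded mRNAs 3 were lower (1 over the list alone, camera adjusted p = 0.266), MT-ND4 by 1.38-fold, its overlapping neighbour MT-ND4L by 1.29-fold and MT-ND5 by 1.22-fold. Leaving out 1 library ended the calls of MT-ND4 (any EV library, FoxQ1 replicate 2 or 3), MT-ND5 (EV replicate 1 or 3, FoxQ1 replicate 2 or 3), ATP5G3 and CYC1 (any EV library, FoxQ1 replicate 2), NDUFB2 (any EV library, FoxQ1 replicate 3), COX6C (EV replicate 1 or 2) and NDUFA11 (EV replicate 2). Over all 18 alternatives the ATP5G3 call was lost in 10 (adjusted p up to 0.413) and the CYC1 call in 8 (up to 0.857). On ranks the mitochondrially encoded list was lower (camera adjusted p = 0.0287), and over its 20 alternatives the adjusted p ranged from 7.4e-05 (without FoxQ1 replicate 1) to 0.933 (with an estimated correlation).

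The share of counts from mitochondrially encoded genes was 4.86 ± 0.357% in EV and 3.66 ± 0.995% in FoxQ1 (SD, n = 3 each). It was 4.77% in FoxQ1 replicate 1 (Wilson 95% interval 4.76 to 4.78, for counting error only), within the EV range of 4.54 to 5.25%, and 3.36 and 2.84% in FoxQ1 replicates 2 and 3. The share of lincRNA counts was 0.37 ± 0.0049% in EV and 0.462 ± 0.062% in FoxQ1. A check list held replication-dependent histone genes, a class whose transcripts largely lack poly(A) tails. Whether the transcripts counted here lacked them was not tested. Of 7 tested members 1 rose (HIST1H2AG, 1.89-fold) and 2 fell (HIST1H2BK, 2.62-fold, and HIST1H1C, 2.06-fold). The list did not pass camera (adjusted p = 0.395) but was lower by fry (adjusted p = 0.0452). Over the list alone the 2 falls passed and the rise did not, and the HIST1H2AG call was lost when any EV library or FoxQ1 replicate 2 was left out (adjusted p up to 0.22).

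Markers of other cell types were mostly scarce. Of 7 tested luminal breast markers 1 rose (XBP1, 1.35-fold) and 2 fell (1 and 3 over the list alone, camera adjusted p = 0.611), among them KRT8. The list's mean log2 fold change was -1.15 against a median of -0.14, so at least 1 member fell far more than KRT8. Of the untested members, KRT19 had 19 reads in EV and 0 in FoxQ1. SPDEF, the only untested one with more reads in FoxQ1, had 6 and 11. XBP1 lies in a raised region of chromosome 22, and with regional medians subtracted its call was lost (log2 fold change 0.03, adjusted p = 0.803). Of 12 blood cell markers only PTPRC, which encodes CD45, was testable, and it fell 48.4-fold, from 10.1 ± 1.01 to 0.204 ± 0.00916 CPM (n = 3 each). No other blood marker had more than 28 reads in a group. Of the endothelial markers only ERG was testable, and it rose 1.49-fold. MBP, the only testable neural crest or glial marker, was at 0.43 ± 0.149 CPM in EV and 0.382 ± 0.167 CPM in FoxQ1 (n = 3 each).

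Neighbouring genes along several chromosomes were shifted together in FoxQ1. Of 313 windows of about 40 genes, 49 had an absolute median log2 fold change above 0.316, the level that the largest window median exceeded in 5% of 1000 random gene orders. These windows, 27 lower and 22 higher, merged into 22 regions holding 2123 genes, 16.4% of the 12945 used. On chromosome 17 from 62293 to 42264085, 384 of 440 genes were lower, with a median log2 fold change of -0.49. That median pools windows of different levels. Window medians lay from -0.709 to -0.619 up to 18639431, and from -0.4079 to -0.319 between 18684308 and 42264085. Every window of chromosome 17 had a negative median and every window of chromosome 22 a positive one, though some missed that level. Relative to each gene's EV mean, the FoxQ1 libraries had medians of -0.48, -0.48 and -0.51 over the region up to 42264085. The EV libraries lay between -0.0048 and 0.0081. Their own mean was the reference, so these values show the spread within EV and not which line moved. Chromosome 18 was higher throughout, with 169 of 198 genes up and a median of 0.49. The strongest window lay on chromosome 7 from 141362722 to 158749438, with a median of -0.75 over 69 genes. Regions on chromosomes 13 (52741844 to 115092796, -0.6) and 14 (19650018 to 64108579, -0.36) were lower, and those on chromosomes 2 (201773696 to 242708231, 0.44), 8 (125551344 to 146281416, 0.45), 11 (118401756 to 122933938, 0.6) and 22 (37447779 to 51239737, 0.38) were higher. With the median of each gene's neighbours subtracted, 6313 genes passed, 5274 of them among the 7132, and 83 of those shared genes had the opposite sign.

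**Figure D4:**
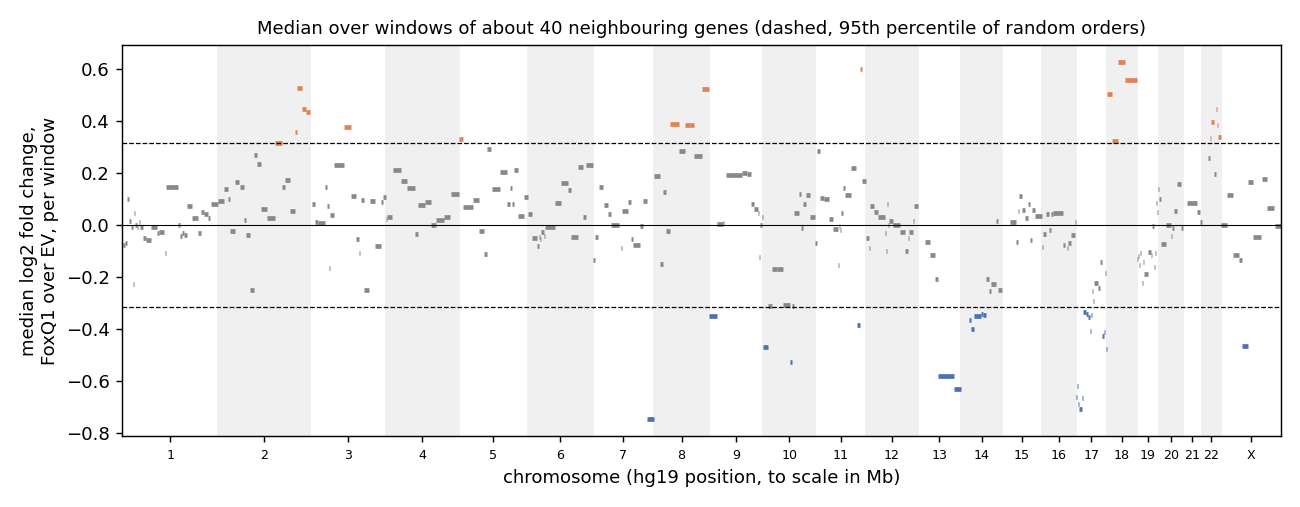
Median log2 fold change of FoxQ1 over EV (vertical) in windows of about 40 neighbouring genes along the hg19 chromosomes (horizontal, in Mb to scale). Bars past the dashed lines at 0.316 and -0.316, the 95th percentile of random gene orders, are orange or blue. The genes of chromosome 18 had a median of 0.49. On chromosome 17 the windows up to 18639431 lay from -0.709 to -0.619, and those between 18684308 and 42264085 from -0.4079 to -0.319.

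The authors' deposited table listed 6638 genes with an adjusted p below 0.05, 3247 higher and 3391 lower. Of these 6372 (96%, Wilson 95% interval 95.5 to 96.4%) also passed in the edgeR fit in the same direction, and 0 passed in the opposite direction. The log2 fold changes of the authors' deposited table correlated with those of the edgeR fit at 0.959 across genes, which are not independent replicates. For FOXQ1 the authors' deposited table gives a log2 fold change of 1.38 with an adjusted p of 2.92e-37.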

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

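The regional and mitochondrial alternatives were chosen after the data were seen, and the others before. FOXQ1 stayed higher and past the threshold in each of the 17 alternatives that kept it. Counts of genes past the threshold stayed within 1.5 times the main 7132, from 5626 without EV replicate 1 to 9409 without FoxQ1 replicate 1. At least 2-fold changes fell from 1823 to 538 with limma on log2(FPKM + 1), 854 with log2(FPKM + 0.1) and 584 without its filter. The share of the authors' calls also made fell or rose from 95.99% to 94.71% with library totals only, 99.88% with DESeq2, 77.75%, 77.7% and 81.08% in the respective FPKM tests, 98.72% without a count filter, 89.15% with mean CPM of at least 1, 72.39% with regional medians subtracted and 95.48% without mitochondrial genes. It ranged from 81.8% to 97.24% with a library left out. Beyond fewer libraries or genes, the cause was not tested.

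Of 11 list calls by camera, 0 remained with an estimated correlation, where 4 lists had an unadjusted p below 0.05, and the adjusted p of the 11 ranged from 0.181 to 0.537. In the stem cell, FoxQ1-linked, G2/M and matrix protease lists the estimate (-0.0164, -0.022, 0.003 and -0.0377) was below the preset 0.01. Their unadjusted camera p still rose, from 0.000173 to 0.0165 for the FoxQ1-linked list. A higher correlation therefore did not remove these calls, and what did was not tested. Camera on ranks lost 4 of the 11 and added the ATF4 list and the mitochondrially encoded mRNAs (9 in all). Fry called 19, the 11 and 8 more. The median of the matrix protease list turned to -0.18 with DESeq2, -0.11 without a count filter and -0.0035 in the unfiltered FPKM test, all settings that test more of its scarce members. With regional medians subtracted, 6 calls among the 149 named genes besides FOXQ1 changed sign: CDH2 (-0.26), NDUFA10 (-0.022), NDUFS1 (-0.0855), ATP5A1 (-0.13), MYBBP1A (0.1) and RPL30 (-0.0676). Of these only CDH2 still passed (edgeR adjusted p = 0.00997), and the others lost their call as well (adjusted p from 0.167 to 0.816). A further 15 of the 149 lost their call there without a change of sign. In the unfiltered FPKM test 14 lost it, and at most 10 with a library left out.

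Deviations from the group mean correlated at 0.0575, -0.0015 and 0.0629 between libraries with the same replicate number. Between different numbers of the 2 groups they correlated at -0.0734 to 0.0245. Not every library correlated best with its own number, so a small shared replicate effect was neither shown nor excluded. With a replicate block, 7506 genes and 14 lists passed, no named gene lost its call and 6980 of the 7132 genes were shared. At 3 libraries per group the simulation, with 50 genes changed at each fold, recovered 56% of 1.5-fold and 84% of 2-fold changes. Many more genes passed in the real comparison, which loosens the cutoff on the unadjusted p, so these rates need not hold there. Recovery was not split by abundance, so a limit set by depth on scarce genes was not measured.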

Other observations

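The tests of random gene order and of cancer-testis families were chosen only after the results were seen. In all, 61 genes, 11 of them named in the comparison, had reads in one group and almost none in the other, taken as a mean CPM of at least 2 against less than 0.2 in every library of the other group. The 38 read only in EV included STS, which encodes steroid sulfatase (23.1 against 0.0572 CPM), the desmosomal gene PKP2 (3.56 against 0.0539 CPM), the chemokine-binding receptor gene DARC (5.8 against 0.0946 CPM) and the cytochrome P450 gene CYP4F11 (6.04 against 0.0782 CPM). The 23 read only in FoxQ1 included the desmosomal cadherin gene DSC2 (0.0131 in EV against 4.04 CPM), the neural adhesion gene NCAM1 (0.0937 against 7.9 CPM), the transcription factor gene KLF8 (0.0263 against 3.98 CPM) and ADAM28 (0.0279 against 4.9 CPM). These genes were chosen after their values were seen, and each value is a mean of 3 libraries.

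The 7132 genes past the threshold were set against other splits of the 6 libraries into 3 and 3. Only 1 of the 10 splits, the real one, gave as many genes by edgeR. The highest of the others gave 0, with 32 to 610 genes at an unadjusted p below 0.05, and no other tool was run on the splits. A total of 10 splits is too few for a share under 0.05. Every other split also mixed EV and FoxQ1 libraries on each side. The difference between the groups then entered the spread within a side, so few calls could arise. The splits therefore cannot decide whether the count arose by chance.

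The shift of neighbouring genes extended over as much as a whole chromosome (chromosome 18), and 0 of 1000 random gene orders gave a window median as large as the observed 0.746, which argues against chance alikeness of neighbours. After a trend on GC content and gene length was removed, the median region kept 96.5% of its shift (48 to 116%), which argues against such a bias as the whole cause. A copy number difference between the EV and FoxQ1 lines predicted that weakly and strongly expressed genes of a region shift alike, and 4 of 66 medians by expression tertile were below 0.5 times their region's median. The exceptions included the strongest region, on chromosome 7, with -0.26 in the lowest tertile against -0.87 and -0.76 in the others. On chromosome 11 from 109964087 to 118397539 the tertile medians were 0.08, -0.63 and -0.19 from low to high expression. The regions were picked for their medians, so most tertile medians would lie near them whatever the cause. A copy number difference therefore remains a hypothesis, with little weight from this count. No DNA was measured here, and regional regulation by FoxQ1 remains open and untested.

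Among the genes read in one group only, a deletion reaching the neighbouring genes would lower those too. The neighbours used were the nearest genes within 500 kb of the genes lost in FoxQ1, with mean CPM of at least 1. Genes themselves read in one group only were left out. Their median log2 fold change was -0.1005, so most neighbours were not strongly lowered. But 13 of the 61 neighbours were below -1, counted without regard to the adjusted p. Of all 14949 tested genes, scarcer ones included, 857 were at least 2-fold lower and also passed the threshold. The rules differ, so the second count is not a matched background for the first. A median cannot show deletions at only a part of these genes, so such deletions were not excluded. A separate history of the EV and FoxQ1 lines might place the genes read in one group only in the shifted regions. Of the 61 genes 14 (23%) lay there against 16.4% of other genes, an odds ratio of 1.52 (95% interval 0.772 to 2.82, Fisher's exact test p = 0.166), an interval too wide to decide. Line history and FoxQ1 cannot be told apart for these genes, nor does the design separate them for any other FoxQ1 against EV difference. The labels do not say whether the groups are pools or single clones, or whether expression was transient or stable, and smaller deletions and silencing were not tested.

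PAGE5, GAGE1 and MAGEC2, cancer-testis genes of chromosome X, were read almost only in EV, so lower expression of these families in FoxQ1 was a candidate explanation. The families, taken by gene symbol, were MAGEA, MAGEB, MAGEC, GAGE, PAGE, XAGE, SSX, CSAG and CTAG, without other MAGE genes. Of their 11 tested members 3 fell and 2 rose, against 49.6% falls among other genes past the threshold. The odds ratio was 1.52 (95% interval 0.174 to 18.2, Fisher's exact test p = 0.685). MAGEA6 rose from 45 ± 2.11 to 56 ± 1.11 CPM and MAGEC1 from 0.308 ± 0.128 to 1.28 ± 0.472 CPM (SD, n = 3 each). With so few members passing, a fall of the families as a group was not decided, and reads shared between near-identical copies were not resolved.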
